A study of Mus musculus with 8 samples.

How the data were processed

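Total RNA of heart tissue was extracted with Trizol, treated with DNase on columns and checked on a Bioanalyzer, and biotin-labelled cRNA was prepared for Illumina bead arrays with an amplification kit, per the labels' protocols. The labels describe each of the 8 samples as a separate numbered mouse, 4 per genotype, and the groups and replicate numbers were taken from the sample descriptions. The deposited table holds, per the file headers, signal intensities that are not normalized and a detection p-value for each of 25697 probes on each array. The values show that the deposited intensities had already been background-subtracted on each array: 29.3% to 31.4% of them were below 0. The detection p-values that the authors deposited move in steps of 0.00125, as 798 negative control beads would give. A second deposited table holds the authors' processed intensities on a linear scale. Its columns share their maximum and have medians from 8.99 to 9.07, and each ranks the probes as the array's own signals do (rank correlation 1), so they were read as quantile-normalized by the authors. The scanner, the software and the authors' method are not given in the sources used here.

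A background correction with neqc had been planned for intensities without correction, with quantile normalization alone as the stated alternative for signals already corrected, and the latter was used. The 8 arrays were quantile-normalized with limma, values under 16 were set to a floor of 16, and log2 was taken, so that the lowest value is 4. The floor was chosen after the values had been seen, and a fold change of a probe near the floor understates the change. Where all values of a genotype lay at the floor, their spread was 0. The p of such a probe rests on the spread of the other genotype and may be too small. Probes were kept when the detection p was under 0.05 on at least 4 of the 8 arrays, which left 9284. Genotype was fitted with limma (lmFit and eBayes, two-sided), and p was adjusted by the Benjamini-Hochberg method over the probes kept, with a threshold of 0.05. No covariate entered the fit. Where a probe was detected on no array of a genotype, the change is given as at least N-fold: the mean of the brighter group against the mean, over the dim arrays, of the higher of the lowest detected level and the probe's own value. Such a bound belongs to the probe, since other probes of the gene can be detected.

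Gene names came from the platform annotation, updated through Entrez identifiers against the mouse RefSeq table of assembly GRCm38.p6, which was used for names and for the order of genes only. Of the probes, 23978 had 1 gene symbol, 0 had several and 1719 had none, and no symbol needed a change. For lists, the brightest kept probe stood for a gene. Among the 43 called genes, 11 had several tested probes, and 0 had a tested probe of the opposite sign. The lists, 37 pathways and 15 cell types or sex-linked genes (960 of 962 symbols matched), were tested with camera of limma at a preset correlation of 0.01 where at least 5 genes were measured. This held for 43 lists, over which p was adjusted. Members were also adjusted over the list alone. That adjustment does not allow for the number of lists and is weakest in the shortest ones.

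The text names Crls1 with all its probes, the 12 genes with the largest rise and up to 12 with the largest fall among those past the threshold, the 4 members of smallest p in each list past the threshold and in the cardiolipin list, Nppa, Nppb, Myh7, Acta1 and Myh6, and the sex-linked genes. Values at the floor count toward the order of the rises. The groups, the limma and camera tests, the 52 lists and this rule were fixed before the data were examined; the floor, the form of the fits without 1 mouse, the added lists and the tests named as later choices were not. Any other gene or probe named here (among them Atf4, Ddit3, Cebpb, Shmt2, Hba-a1 and the genes of the last part) was chosen after its values were seen.

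Correlations between arrays over the probes kept ran from 0.970 to 0.985, and no arrays were identical. The numbers of the mice fall into 2 runs of consecutive numbers with 2 mice of each genotype in each, which may reflect litters, though the labels do not say so. The runs were used as a block and for values within each run. The fit was checked on 20 simulated data sets of 9284 probes, with 200 probes changed. They took the WT means and the spreads within genotypes, with small spreads raised to a minimum, and noise independent between probes. Probes without spread at the floor are thus not represented. Of probes changed by a log2 of 0.5, 14.4% were called, against 64.7% at 1 and 88.1% at 2. On average 6.14% of the calls were false, and 0 probes were called in any data set without changes. For the list test, noise was drawn independently for each gene and 1 list, the integrated stress response and amino acid synthesis list, was shifted by 0.5. It was called in 100% of simulated data sets. As members of the real lists can be correlated, this rate does not carry over to them.

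The alternatives were log2 of the signal plus 16 without the floor, equal array medians, neqc with an offset of 50, the authors' processed intensities, no detection filter and a stricter one, the replicate number or the mouse number run as a block, eBayes with trend and robust settings, array weights, leaving out each mouse, an estimated correlation, fry, and averaged probes. Sex as a covariate was not run, since sex could not be read. Exact permutation tests used all assignments of 4 mice of 8. Work was done in R 4.3.3 with limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9.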

Results

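RNA of heart tissue was profiled on Illumina mouse bead arrays, which read transcripts through probes bound to beads. The hearts came from 8 mice of the C57BL/6J background at 4 months of age. In 4 mice a transgene expressed human cardiolipin synthase 1 in the heart (Tg-CLS), and 4 wild-type littermates (WT) served as controls. Cardiolipin synthase makes cardiolipin, the phospholipid typical of the inner mitochondrial membrane. Each array held 25697 probes, of which 8862 to 10048 were detected above background. The mean was 9137 ± 450 probes in WT and 9644 ± 351 in Tg-CLS (SD, n = 4 each; exact two-sided permutation p = 0.143). The mean signal per probe was 177 ± 14.5 in WT and 196 ± 12.6 in Tg-CLS (SD, n = 4 each; exact two-sided permutation p = 0.114).

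The question put by the design was which cardiac transcripts differ when human cardiolipin synthase is expressed in the heart. The Crls1 signal itself, the mouse gene for this enzyme, was read first. A Crls1 probe (ILMN_1219797) was not detected on any of the 4 WT arrays and was detected on all 4 Tg-CLS arrays. Its normalized log2 intensity was 4.05 ± 0.064 in WT, close to the floor of 4, and 7.75 ± 0.32 in Tg-CLS (SD, n = 4 each), at least 10.7-fold higher. Against the floor the fitted log2 difference was 3.69 (limma, adjusted p = 5.40e-06), a size that follows the chosen floor, so that only the bound stands as a measured fold. The exact two-sided permutation p over the 8 mice was 0.0286, the smallest that 4 against 4 can give. The other 2 tested Crls1 probes had log2 fold changes of 0.16 (ILMN_3062470, limma adjusted p = 0.844) and 0.15 (ILMN_1231132, limma adjusted p = 0.879). A further Crls1 probe (ILMN_3140091) was detected on 1 array of each genotype and was not tested. The sequences of these probes were not used here, so which of them can bind the human transcript was not read from the files.

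**Figure D1:**
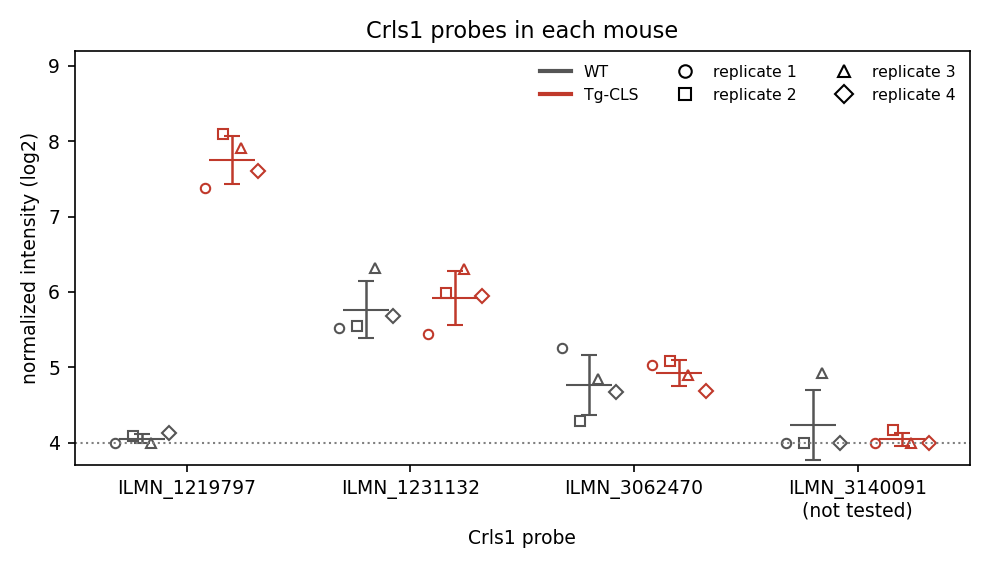
Normalized log2 intensity (vertical axis) of the 4 Crls1 probes (horizontal axis) in each WT mouse (grey) and each Tg-CLS mouse (red); symbols mark replicates, bars the mean and SD of 4 mice, and the dotted line the floor of 4. Probe ILMN_1219797 lies near the floor in WT and at 7.75 ± 0.32 in Tg-CLS, and the other probes overlap between the genotypes.

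Among named genes other than Crls1, those with the largest rises in Tg-CLS hearts included enzymes and carriers of amino acid and one-carbon metabolism and genes of stress signalling, beside the DNA repair gene Brca2. The largest rise of all was that of a probe without a gene name. Asns, which makes asparagine, and Mthfd2, a mitochondrial enzyme of the folate cycle, were not detected in any WT heart and were at least 4.75-fold and at least 5.54-fold higher in Tg-CLS. Slc7a5, a carrier of large neutral amino acids, rose 6.13-fold, and the transcription factor Atf5 rose 5.01-fold. The largest falls were those of Lypd2 (3.15-fold), of Ppp1r1b, which encodes the phosphatase inhibitor DARPP-32 (2.30-fold), and of Urah, a hydrolase of urate breakdown (2.24-fold). In all, 51 of 9284 tested probes passed the limma test at an adjusted p under 0.05, 39 higher in Tg-CLS (32 named genes and 4 probes without a gene name) and 12 lower (11 named genes and 1 probe without a name). Of the 39 higher probes, 11 were detected on no WT array, and of the 12 lower probes, 2 were detected on no Tg-CLS array.

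Further rises named by the rule were those of Trib3, a pseudokinase of stress signalling (log2 fold change 2.28 ± 0.19, SE), Chac1, which degrades glutathione (1.85 ± 0.19), Phgdh, the first enzyme of serine synthesis (1.52 ± 0.20), and Aldh18a1, an enzyme of proline synthesis (1.42 ± 0.16), with limma adjusted p from 4.54e-04 to 0.0104. Trib3 and Phgdh were each detected on 1 of 4 WT arrays, so that the sizes of their rises depend on the floor. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by a log2 fold change of 1.78 ± 0.25 and 1.28 ± 0.11 on its called probes (limma adjusted p = 0.0150 and 4.54e-04). Aldh1l2, a mitochondrial folate enzyme, rose at both tested probes, 3.45-fold on the probe that WT hearts detected and at least 3.90-fold on the other, which they did not. Brca2, a DNA repair gene, was at least 4.28-fold higher on a probe not detected in WT (limma adjusted p = 1.20e-05), and its other tested probe, detected on 2 WT arrays, had a log2 fold change of 1.12 ± 0.21 (adjusted p = 0.0553). The other falls were those of Tmem82, Fah, Slc4a1, Hr, Tnnt1, Scn4b, Alas2 and Cd274, with log2 fold changes from -1.10 to -0.66 and limma adjusted p from 0.00951 to 0.0404; Alas2 and Cd274 did not pass in any of the 8 fits that left out 1 mouse. The called Hr probe was detected on 1 of 4 Tg-CLS arrays. A brighter Hr probe, detected on all 8 arrays, had a log2 fold change of -0.46 ± 0.19 (SE, limma adjusted p = 0.430). Fah is an enzyme of tyrosine breakdown, Tnnt1 the slow skeletal troponin T and Scn4b a beta subunit of the sodium channel. Slc4a1, the anion exchanger of red cells, was not detected in any Tg-CLS heart and was at least 1.87-fold higher in WT. Among the erythroid markers, Slc4a1 and Alas2, the haem synthesis enzyme of red cell precursors, thus fell, and Hba-a1, an alpha globin, had a log2 fold change of -0.28 ± 0.11 (limma adjusted p = 0.376). All 3 measured erythroid markers were lower when adjusted over the list alone, an adjustment over 3 genes only, and this list was too short for a list test.

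**Figure D2:**
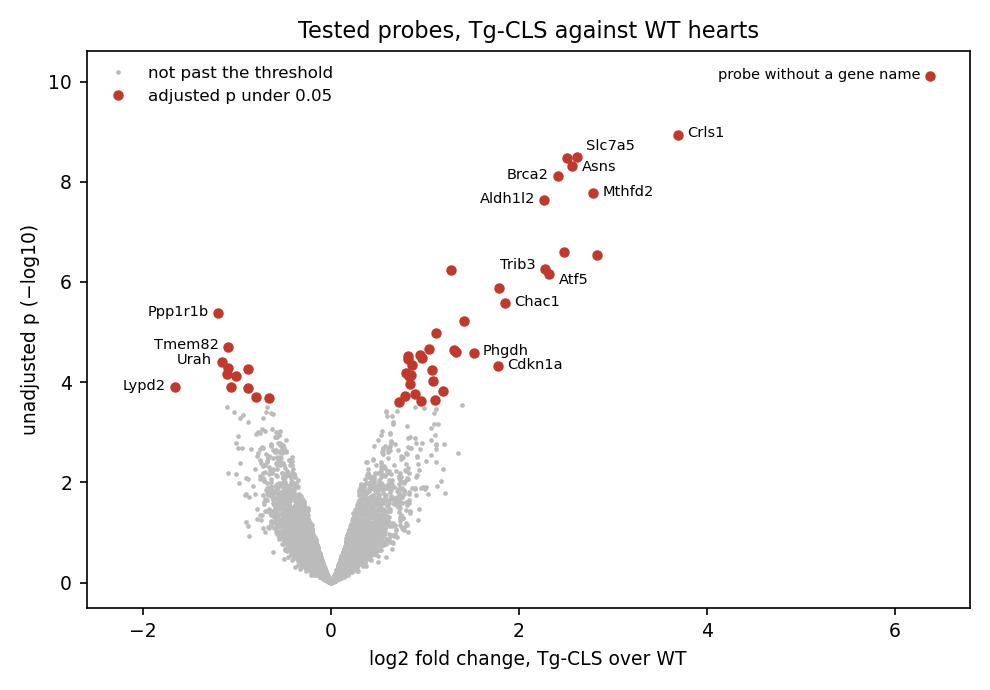
Log2 fold change, Tg-CLS over WT (horizontal axis), against the unadjusted limma p on a −log10 scale (vertical axis) for the 9284 tested probes; red points are the 51 probes at an adjusted p under 0.05, and grey points the rest. The called probes with the largest changes lie on the side of higher signal in Tg-CLS, 39 against 12, and the point farthest out is a probe without a gene name (6.37, against the floor in WT).

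Among the fixed gene lists, the integrated stress response and amino acid synthesis list moved most. Of its 14 measured members 12 rose, none fell, and 2 did not pass; adjusted over the list alone, 13 rose. Its median log2 fold change was 1.27, and it held Asns, Mthfd2, Atf5 and Trib3 as the members of smallest p. Atf4, the central transcription factor of this response, rose 1.72-fold (limma adjusted p = 0.0384, but 0.0627 to 0.115 in the 8 fits that left out 1 mouse, none of which called it) and Ddit3, which encodes CHOP, rose by a log2 fold change of 0.85 ± 0.13 (SE). The values were 0.46 ± 0.14 for Cebpb (log2 fold change with SE, limma adjusted p = 0.277) and -0.24 ± 0.20 for Shmt2 (adjusted p = 0.731). The list lay higher than the other genes (camera of limma, adjusted p = 9.30e-30), and its call held with an estimated correlation (adjusted p = 0.00616 with an estimated correlation). Its median was 1.38 and 1.27 within the 2 runs of consecutive mouse numbers, each with 2 mice per genotype. In the list of the unfolded protein response of the endoplasmic reticulum, 8 of 18 genes were measured and the rest could not be read. The measured members had a median of -0.090, and none passed the threshold (camera adjusted p = 0.624 for the list).

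**Figure D3:**
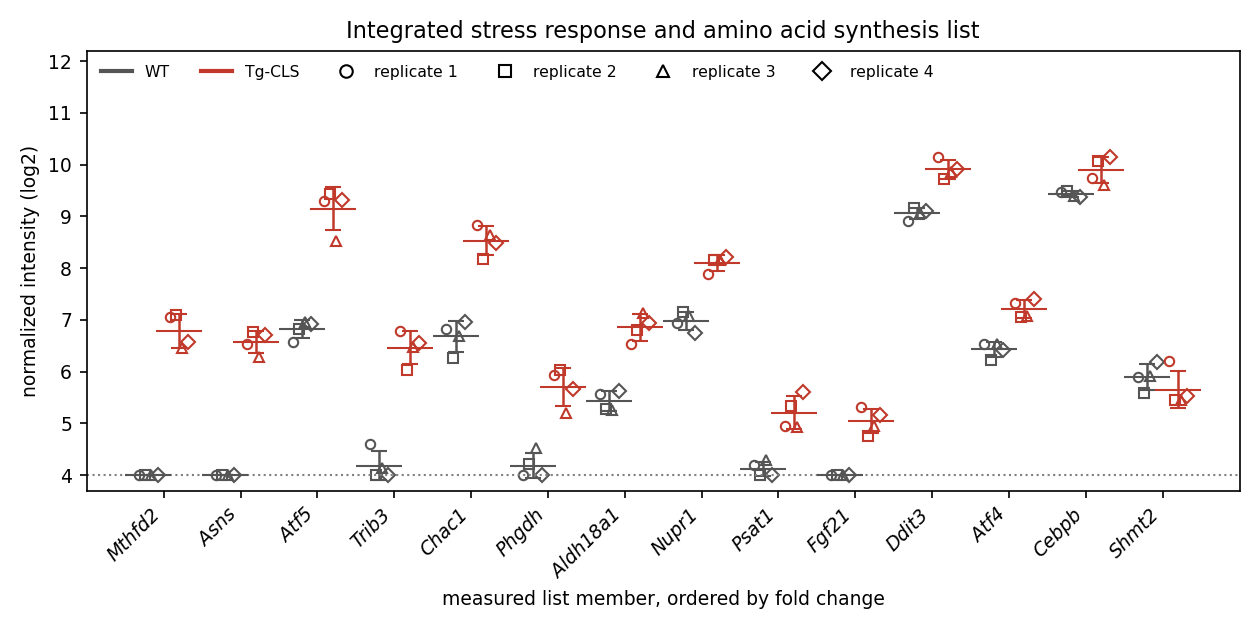
Normalized log2 intensity (vertical axis) of the 14 measured members of the integrated stress response and amino acid synthesis list, ordered by fold change (horizontal axis), in each WT mouse (grey) and each Tg-CLS mouse (red); symbols mark replicates, bars the mean and SD of 4 mice, and the dotted line the floor of 4. In 12 members, at a limma adjusted p under 0.05, the 4 Tg-CLS mice lie above the 4 WT mice, and Cebpb and Shmt2 did not pass.

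Of 43 lists tested, 6 passed the camera test, 3 higher and 3 lower in Tg-CLS, and with an estimated correlation the stress response list alone passed. The estimated correlation was 0.14 for the ribosome list and 0.10 for the interferon list. It was 0.0071 for fatty acid oxidation, -0.014 for antioxidant genes and -0.070 for ion channels, below the preset 0.01. A higher correlation between members thus does not account for the loss of these 3 calls. Cytosolic ribosomal protein genes lay higher, with a median log2 fold change of 0.19 over 39 members and 34 of them above 0 (adjusted p = 4.35e-07; adjusted p = 0.266 with an estimated correlation). None of these members passed singly, over all genes or adjusted over the list alone, the values of smallest p being those of Rpl3 (0.55 ± 0.13, log2 fold change with SE), Rpl22 (0.44 ± 0.14), Rplp1 (0.32 ± 0.10) and Rps13 (0.33 ± 0.11). Cardiac ion channel and gap junction genes lay lower, with a median of -0.29 over 13 members (adjusted p = 5.21e-04; adjusted p = 0.103 with an estimated correlation). In that list 1 member, Scn4b, fell (2 adjusted over the list alone), and the values were -0.78 ± 0.19 for Kcnj3, -0.90 ± 0.31 for Kcne1 and -0.37 ± 0.14 for Kcnk3, all potassium channel subunits. Kcnj3 was detected on 3 of 4 Tg-CLS arrays and lay near the floor there. Interferon-stimulated genes lay lower, with a median of -0.44 over 15 members (adjusted p = 5.21e-04; adjusted p = 0.266 with an estimated correlation). No interferon-stimulated gene passed over all genes and 5 fell adjusted over the list alone, the smallest p belonging to Ifit3 (-0.51 ± 0.12), Gbp2 (-0.52 ± 0.13), Usp18 (-0.43 ± 0.13) and Rsad2 (-0.51 ± 0.15). Among immune cell markers, both measured neutrophil genes, Mmp9 and S100a8, were lower (median -0.52), and Mmp9 fell adjusted over the list alone. Both lay near the floor and overlapped between the genotypes. Within the 2 runs of mouse numbers the log2 fold changes were -0.14 and -0.92 for Mmp9 and -1.01 and -0.020 for S100a8. Of 9 macrophage markers 7 were lower (median -0.11, camera adjusted p = 0.432).

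Mitochondrial fatty acid oxidation genes lay lower, with all 18 measured members below 0 and a median log2 fold change of -0.17 (camera adjusted p = 0.00427; adjusted p = 0.171 with an estimated correlation). None passed singly, over all genes or adjusted over the list alone; the values were -0.43 ± 0.15 for Acaa2, -0.30 ± 0.11 for Decr1, -0.27 ± 0.12 for Acads and -0.22 ± 0.12 for Ech1 (SE). Beside this list and the ion channel list, the ventricular cardiomyocyte markers had a median of -0.16, with 7 of 8 lower (camera adjusted p = 0.273), and the sarcomere and adult contractile genes one of -0.11, with 13 of 15 lower (camera adjusted p = 0.0654). Atrial cardiomyocyte markers had a median of -0.14, with 4 of 7 lower (camera adjusted p = 0.656). The antioxidant and NRF2 target genes lay higher, with a median of 0.17 over 16 members (camera adjusted p = 0.0473; adjusted p = 0.266 with an estimated correlation). No antioxidant gene passed over all genes and 1 rose adjusted over the list alone; Srxn1 stood at 0.63 ± 0.14, Nqo1 at 0.57 ± 0.17, Gsta4 at 0.24 ± 0.13 and Gpx4 at 0.21 ± 0.13. Within the 2 runs of mouse numbers the medians were 0.27 and 0.017 for this list, 0.11 and 0.25 for the ribosome list, -0.26 and -0.42 for ion channels, -0.21 and -0.38 for interferon-stimulated genes and -0.13 and -0.17 for fatty acid oxidation. The call of the antioxidant list was lost without WT replicate 3 (adjusted p = 0.101) and in 5 of the other 7 fits that left out 1 mouse.

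**Figure D4:**
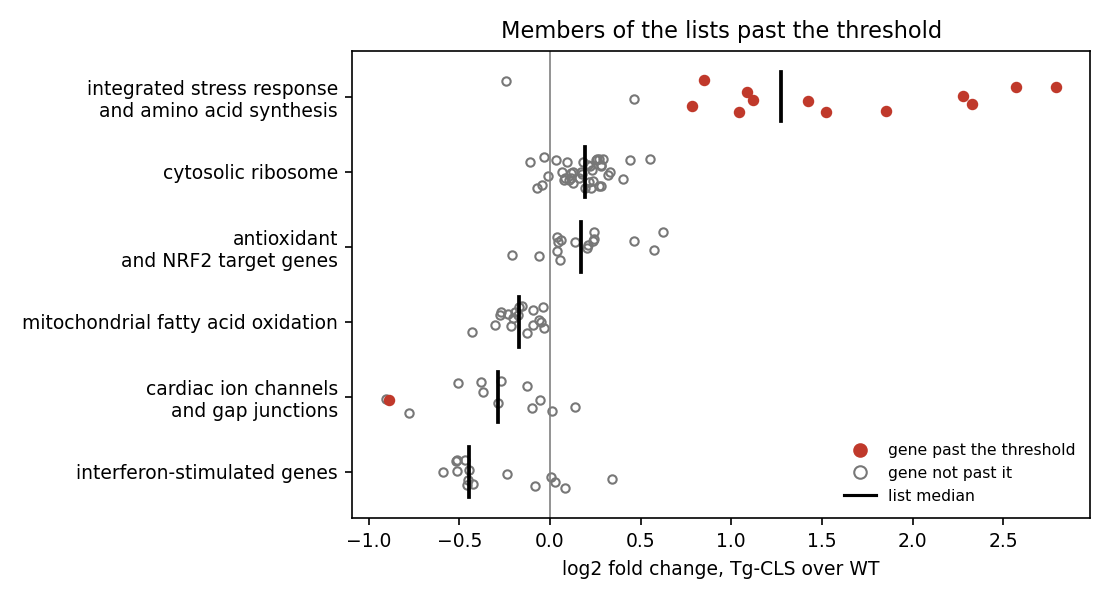
Log2 fold change, Tg-CLS over WT (horizontal axis), of each measured member of the 6 lists past the camera threshold (vertical axis); red points are genes at a limma adjusted p under 0.05, open points the rest, and black bars the list medians. The median of the stress response list is 1.27, and those of the other 5 lie between -0.44 and 0.19.

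Of the 10 measured genes of cardiolipin synthesis and remodelling, Crls1 rose, on the probe ILMN_1219797 alone, and 9 did not pass. Adjusted over the list alone, Crls1 was again the only member that rose. After Crls1 the smallest p belonged to Prelid1 (0.21 ± 0.11, log2 fold change with SE), Pnpla8 (0.22 ± 0.14) and Taz, the cardiolipin transacylase tafazzin (-0.15 ± 0.11). The list as a whole did not pass (camera adjusted p = 0.273); its mean log2 fold change was 0.38, its median was -0.0087, and without Crls1 its mean was 0.011. Subunits of the respiratory chain did not move as lists: the medians were -0.016 for complex I (29 members), -0.051 for complexes II and III (10 members), 0.013 for complex IV (14 members) and 0.043 for ATP synthase with the nucleotide carriers (17 members), with camera adjusted p from 0.571 to 0.760. Of the 6 cell type lists long enough to test, none passed. Endothelial markers had the smallest p, with a median of -0.18 over 11 members (camera adjusted p = 0.0845).

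The fetal gene programme, which is switched on again in stressed hearts, did not pass as a list (median log2 fold change 0.036 over 13 members, camera adjusted p = 0.994). In it Tnnt1 fell and 12 members did not pass, in both counts. The log2 fold changes were 0.058 ± 0.21 for Nppa, 0.12 ± 0.30 for Nppb, 0.033 ± 0.43 for Myh7 and 0.14 ± 0.48 for Acta1 (SE), with limma adjusted p from 0.945 to 0.990. The adult myosin gene Myh6 stood at -0.32 ± 0.15 (limma adjusted p = 0.495). Values of the 4 stress genes spread more between Tg-CLS mice than between WT mice, with an SD of 0.45 against 0.091 for Nppa and of 1.10 against 0.42 for Acta1. Across the 4 Tg-CLS mice, 6 atrial markers other than Nppa had correlations from 0.026 (Tbx5) to 0.946 (Dkk3) with the mean of these genes, with a median of 0.881. The sign of these 4 differences depended on single mice: without Tg-CLS replicate 3 they were -0.11 for Nppa, -0.11 for Nppb, -0.20 for Myh7 and -0.15 for Acta1. The sex of the mice could not be read, since Xist and 3 of the Y-linked genes were undetected on all 8 arrays and Uty was detected on 1.

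**Figure D5:**
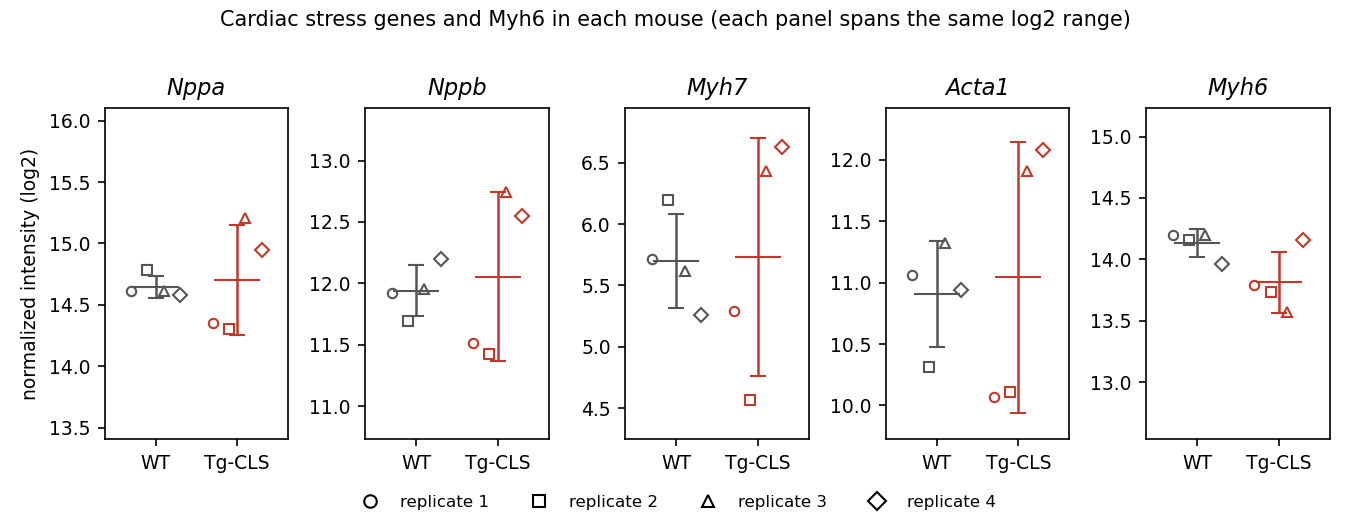
Normalized log2 intensity (vertical axis, each panel spanning the same range) of Nppa, Nppb, Myh7, Acta1 and Myh6 in each WT mouse (grey) and each Tg-CLS mouse (red); symbols mark replicates and bars the mean and SD of 4 mice. For Nppa, Nppb, Myh7 and Acta1, Tg-CLS replicates 3 and 4 lie above replicates 1 and 2, and the genotype means differ by 0.033 to 0.14.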

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

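The tests on values at the floor, on the Brca2 neighbourhood, on the spread of stress genes and on splits for the probe count were chosen after the results had been seen; those on array brightness, on another transgene and on splits for the list count were chosen before. Of the 35 ways to part the 8 mice into 4 and 4, only the real one gave as many as 51 probes past the threshold. The highest other split gave 10, which argues against chance for that count. It does not exclude chance, since 1 of 35 is the smallest share these mice can give and the test was chosen after the result. At an unadjusted p under 0.05 the real split gave 962 probes and the highest other, WT replicate 1 with Tg-CLS replicates 2, 3 and 4, gave 888. For the 6 lists, 4 of the 35 splits gave as many and the highest other gave 10, so chance cannot be excluded for the number of lists. Taken singly, the stress response, fatty acid oxidation and ion channel lists had a camera p in the real split that no other split reached. The ribosome, antioxidant and interferon lists each had 1 other split with a smaller p.

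The rise of the integrated stress response list was weighed first. Values of WT at the floor were argued against by the 8 members above the floor on all 8 arrays, whose median log2 fold change was 0.99 with 6 of them past the threshold. Brighter Tg-CLS arrays were argued against by the values before any scaling between arrays, where all tested probes had a median of 0.14 and the list one of 1.43. Whether any transgene, its insertion or its promoter would give the same rise cannot be told apart from an effect of the enzyme, because 0 groups carried another transgene or an inactive enzyme. An effect of the expressed enzyme, the biological difference the design names, stays open in the same way.

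Brca2 and N4bp2l1, neighbours on the chromosome, were both higher in Tg-CLS (N4bp2l1 by 1.31 on the log2 scale). A single cross-reacting probe was argued against by the other tested Brca2 probe, at a log2 fold change of 1.12 ± 0.21 (SE, limma adjusted p = 0.0553). A change over the whole neighbourhood was argued against by the 7 nearest tested genes, up to 5 on each side, with a median of -0.032 and a range from -0.41 to 0.36. Chance adjacency stays open, as random draws of 43 tested genes held at least 1 adjacent pair with a permutation p of 0.24. No biological explanation of the pair was tested.

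Nppa, Nppb, Myh7 and Acta1 spread more between Tg-CLS mice than between WT mice, with SD ratios from 2.52 to 4.98. In all 4 genes Tg-CLS replicates 3 and 4 lay above replicates 1 and 2, so the genes are not separate observations. Chance was not tested for this spread, which rests on 4 mice per genotype and was picked after it had been seen. A larger spread of all genes in Tg-CLS was argued against by the median SD ratio of 1.01 over the tested genes above the floor, a measure put in place of the rank among random gene sets after that rank (100%) had been seen. A varying share of atrial tissue cannot be told apart from other causes: the 6 atrial markers other than Nppa had a median SD ratio of 0.744, since they also varied between WT mice, but followed the 4 genes across the 4 Tg-CLS mice with a median correlation of 0.881. That correlation was taken within Tg-CLS only. Between WT mice the SDs were 0.27 to 0.65 for these markers, 0.091 for Nppa and up to 0.42 (Acta1) for the other stress genes. A difference in cardiac stress between Tg-CLS mice may underlie the spread and was not tested.

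Single values far from the other 3 of their group were found in 10 of 141 groups of 4 values, and chance gives about 1 in 20 (7.05 here). In Tg-CLS these were Atf5 in replicate 3 (8.53, others 9.29 to 9.43), Rpl3 in replicate 4 (11.28, others 10.92 to 10.95), Rplp1 in replicate 4 (14.71, others 14.85), Gbp2 in replicate 2 (8.28, others 8.61 to 8.67), Aldh1l2 on its brighter probe in replicate 3 (7.05, others 6.78 to 6.79) and Per2 in replicate 1 (7.84, others 8.17 to 8.21), all as log2 intensities. In WT they were Kcne1 in replicate 3 (7.23, others 6.51 to 6.63), Gbp2 in replicate 3 (9.23, others 8.98 to 9.02) and Nppa in replicate 2 (14.78, others 14.58 to 14.61). WT replicate 1 had 9809 detected probes against 8862 to 8961 on the other WT arrays.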

How the results depend on the processing

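The neqc fit with offset 16, floors of 8 and 32 and the fits of the cardiolipin list without Crls1 were chosen after the data had been seen. The leave-one-out fits first applied the filter anew, and holding the tested probes fixed was chosen after those counts had been seen. The 51 probes became 136 (79 higher, 57 lower) with neqc at offset 50 and 153 with trend and robust eBayes settings. Without the detection filter they became 19, with 25697 probes in the fit and in the adjustment. The cause of these changes was not tested, though the neqc fits corrected signals for background that had already been background-subtracted. With the replicate number as a block the count was 16, but the numbers do not pair the mice: the correlations of deviations of same-numbered mice ran from -0.11 to 0.063, and 1 of 8 samples correlated best with its own number. With the mouse number run as a block it was 48 (38 higher, 10 lower), 46 of them among the 51, and the 6 lists passed. Leaving out 1 mouse gave 32 to 51 probes on the same 9284 probes, with 32 without WT replicate 4, Tg-CLS replicate 2 or Tg-CLS replicate 4. With the filter applied anew to 7 arrays the range was 13 to 55, with 31 without WT replicate 4; a probe seen in Tg-CLS alone then fails the filter when a Tg-CLS mouse is left out. The 6 lists became 10 with neqc at offset 50, 11 without the filter (52 lists tested), 1 with an estimated correlation and 10 with fry, and 5 to 8 without 1 mouse. The Crls1 probe stayed past the threshold wherever it was tested. Its fitted log2 difference ran from 3.56 to 3.83 without 1 mouse and from 2.05 (neqc at offset 50) to 4.19 (floor of 8) over all alternatives; as WT lay at the floor, these sizes follow the floor or offset and are not measured folds. It has no value with detection required on all 8 arrays. No called probe turned its sign under any alternative. Of the 50 called probes other than Crls1, 24 stayed past the threshold in all 8 leave-one-out fits on the same probes and 26 were lost in at least 1, while 13 passed under every alternative that tested them; Atf4, Alas2, Cd274, Depp1 and Bud23 were lost in all 8. The stress response list held 13 of the called probes; this count was 10 to 12 without 1 mouse, 5 to 7 without a Tg-CLS mouse when the filter was applied anew, 6 with the replicate number as a block or detection required on all 8 arrays, and 5 without the filter, and 5 of the 13 passed under every alternative that tested them.

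Signs turned only for values near 0. Nppa ran from -0.11 to 0.19 without 1 mouse, Nppb from -0.11 to 0.33, Myh7 from -0.26 to 0.42, Acta1 from -0.21 to 0.45, and the second Crls1 probe (ILMN_3062470) from -0.0012 to 0.32. Nppa was -0.086 and Myh7 -0.0045 with equal array medians, Myh7 was -0.066 with array weights, and that Crls1 probe was -0.038 with a floor of 32; the cause was not tested. The fetal list, with a mean of 0.028, ran from -0.092 to 0.16 without 1 mouse and was below 0 with averaged probes (-0.0011) and equal array medians (-0.0012). The direction that the list test gave for it turned with array weights (mean 0.0022), fry (mean 0.028) and averaged probes. The mean of the cardiolipin list, 0.38, became 0.044, 0.0092, 0.0026 and 0.045 without Tg-CLS replicates 1 to 4 and 0.025 with a floor of 8, because the probe ILMN_1231132 then stood for Crls1. That list passed with equal array medians (adjusted p = 0.0332), neqc at offset 50 (0.0258) or 16 (0.0451) and fry (0.00530), and without Crls1 in none of these (adjusted p from 0.504 to 0.938).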

Other observations

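The lists and genes in this part, and the test of synthetases, were chosen after the results had been seen. Genes grouped as cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, lay higher in Tg-CLS hearts. Of 15 measured, 5 rose over all genes (Sars 1.94-fold, Iars 1.96-fold, Nars 1.77-fold, Gars 1.77-fold and Eprs 1.74-fold, limma adjusted p from 0.0110 to 0.0182), and the median log2 fold change was 0.56. Adjusted over the list alone, 8 rose. Here and in the test below, Gars and Kars, which each also encode the mitochondrial enzyme, were counted as cytosolic. The values were 0.64 ± 0.15 for Aars and 0.82 ± 0.23 for Mars1, which did not pass, and -0.055 ± 0.23 for Kars and 0.0015 ± 0.26 for Hars (log2 fold change, SE). The 10 measured mitochondrial synthetases had a median of -0.16, with 8 of them lower and no member past the threshold. Among amino acid transporters 2 of 6 measured rose, Slc7a5 and Slc1a4, a carrier of neutral amino acids that WT hearts did not show above background (at least 1.72-fold higher). Of the mitochondrial one-carbon enzymes Mthfd2 and Aldh1l2 rose and Shmt2 did not pass, and of 4 measured cytosolic ones none passed over all genes (Shmt1 0.76 ± 0.23, limma adjusted p = 0.288) and 1, Shmt1, rose adjusted over the list alone. The difference between these 2 sets was not tested.

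An equal change of the cytosolic and the mitochondrial synthetases was argued against. The mean of the 14 cytosolic minus that of the 8 mitochondrial members above the floor on all 8 arrays was 0.62 higher on the log2 scale in Tg-CLS, with SDs of 0.14 in WT and 0.082 in Tg-CLS (n = 4 each) and all 4 Tg-CLS mice above every WT mouse. With all 15 and 10 members the difference was 0.67 (exact two-sided permutation p = 0.0286, the smallest possible here). The mean log2 fold change was 0.46 over these 15 cytosolic and -0.20 over these 10 mitochondrial members. The larger part of the difference thus came from higher cytosolic values. Since both sets were chosen after their values had been seen, the p supports no cause, and whether the mitochondrial set fell stays open.

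Fgf21, a hormone that fasted and stressed tissues secrete, was not detected in WT hearts and was at least 1.65-fold higher in Tg-CLS (limma adjusted p = 0.0101), and Nupr1, a stress-induced chromatin protein, rose 2.18-fold. In the clock list Per2 rose 1.79-fold (limma adjusted p = 0.0256), while the log2 fold changes of Nr1d1 (-0.68 ± 0.12, adjusted p = 0.0533), Nfil3 (0.47 ± 0.14) and Dbp (-0.32 ± 0.14) did not pass (SE). Adjusted over that list alone 2 members rose and 1 fell, and the list as a whole did not pass (camera adjusted p = 0.886). In the immediate early list none of 10 measured genes passed over all genes and 4 rose adjusted over the list alone, among them Klf4 (0.80 ± 0.20).

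The largest change of all tested probes belonged to ILMN_2835384, which has no gene name in the annotation used. It was detected on all 4 Tg-CLS arrays (log2 intensity 10.37 ± 0.46, SD, n = 4) and on no WT array, at least 66.3-fold higher (limma adjusted p = 7.23e-07). The sequences of the unnamed probes were not used here, so whether any of them binds the transgene construct was not read. The other unnamed probes past the threshold were ILMN_1225528, ILMN_2735350 and ILMN_1227282, which rose, and ILMN_2654624, which fell.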
